A study of Arabidopsis thaliana with 8 samples.

How the data were processed

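The series holds 8 two-colour Agilent 44K Arabidopsis arrays. Per the labels' protocols, plants were grown on GM medium at 22 °C with 16 h light and 8 h dark after 3 days of stratification at 4 °C, extracts were cleared at 15000 × g and separated on a 26.25 to 71.25% sucrose gradient for 50 min, and 8 fractions were collected. Fractions 5 to 8 were pooled as the polysome fraction and fractions 1 to 8 as the total fraction. An RNA spike-in mix (5 µl) was added to each pool at collection, mix A to the polysome and mix B to the total fraction. Per the labels' protocols, 500 ng of RNA was amplified from an oligo(dT) primer, with polysomal RNA labelled with Cy3 and total RNA with Cy5. No array had the dyes swapped. A gene's dye effect is therefore part of its ratio on every array, so no ratio was tested against 0, and only differences between groups, in which a constant dye effect cancels, were tested. Groups and replicate numbers came from the labels, and the series description states 2 biological replicates per group.

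The scanner files were deposited as Agilent Feature Extraction output (version 10.10.1.1, per the file headers). They hold linear spot intensities of both channels as deposited, median spot and background signals, processed signals that the software had background-subtracted and dye-normalized, and a log10 ratio of Cy5 over Cy3, per the file headers. Quality flags are other values in the deposited files. The log10 ratio deposited by the authors was used only to check directions. A table of the authors' deposited linear ratio of each spot was also used. Its log2 values correlated at -1.00 with Agilent's log ratio of Cy5 over Cy3 on every array, which gives its direction as polysomal over total. It listed only spots well above background in both channels. Its values were not centred on 1, and the scaling behind them is not given in the sources used here. No column of per-sample values was left unused. Each array had 45220 spots, 1417 of them controls, and 43603 gene probes.

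Median spot signals were corrected with normexp (offset 50) in limma 3.58.1 under R 4.3.3 and normalized within arrays by loess, with control and outlier-flagged spots at weight 0. The files hold median and not mean spot signals, so median signals were used in the alternatives planned on mean signals too. Loess sets the bulk of genes on each array to a ratio near 1, so a shift of all genes between stages is removed and was measured separately against the 10 spike-in probes (32 spots each), without loess. The offset of 50 understates the fold changes of dim genes. Outlier-flagged spots were left out, and spots of a probe were averaged. Probes were named through the RefSeq transcript accession in the scanner files and a table of the TAIR10.1 assembly: 34392 of 35659 probes with such an accession matched, for 25426 loci, and 9211 probes had no locus. The array design was built on an earlier TAIR10 release, so no coordinates are printed and loci are given by their code. No plastid- or mitochondrion-encoded locus was among the named probes, and those 2 lists had no measured member. For the polysome ratio, genes well above background in both channels on all 8 arrays were tested, with the brightest probe per gene. Of 4640 genes with a second probe, the changes of both probes correlated at 0.83 in 2DAG against 21DAG and 0.73 in Young against Mature leaves, and 7.88% and 3.55% of called genes with a second probe had the opposite sign there. Total levels are Cy5 log2 values after loess and quantile normalization of the mean intensity, for genes well above background in Cy5 on both arrays of at least 1 group.

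A linear model with 1 coefficient per group was fitted to all 8 arrays with limma (lmFit and eBayes), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Gene lists of at least 4 tested genes were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were alternatives. Camera sets a list against the other genes, while fry tests only whether the list's own genes changed. With an estimated correlation, camera also refers its statistic to the few residual degrees of freedom of the fit. Its p-values therefore rise even where the estimated correlation is near 0. The group comparisons, the lists, the naming rule and the alternatives other than 2 chosen later were fixed before the data were examined. The later alternatives were the centred deposited ratios and the median centring of Cy5. Since the deposited ratios follow Agilent's log ratio so closely, once centred they nearly repeat the processed signals and are not a separate check. The lists were cytosolic and plastid ribosomal proteins, translation factors, ribosome biogenesis, light harvesting and photosynthetic electron transport, the Calvin cycle, seed storage and late embryogenesis, storage lipid mobilisation, the cell cycle and DNA replication, core histones, the proteasome, conserved upstream open reading frames, cell wall expansion, leaf senescence, salicylate and pathogen defence, heat shock and chaperones, the circadian clock, stomatal lineage and guard cell markers, and markers of roots, flowers and inflorescences and the shoot meristem. Seed storage, root, flower and shoot meristem lists had fewer than 4 genes in the ratio test. Genes were named by a rule: in each ratio comparison, among genes past the threshold with both arrays of one group beyond both of the other and with a symbol other than the locus code, the 8 largest rises and 8 largest falls, and from each list its member with the smallest adjusted p; for total levels, 5 and 5 among genes well above background in Cy5 on all 4 arrays compared. If fewer than 4 had passed in a direction, the 4 with the smallest p were to be named as not passing. Probes whose transcript accession matched several loci were not named. Probe sequences were not checked, so a named probe may also match other loci. Genes named in one comparison could be followed in others.

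The steps were tested on simulated data. In simulated ratios of 15665 genes, changes of 0.3 on the log2 scale were recovered in 34.3% of genes in both comparisons, changes of 0.6 in 85.1% (2DAG against 21DAG) and 88.1% (Young against Mature leaves), and changes of 1 in 100%, with 5 and 8 false calls. In simulated total levels of 19794 genes, changes of 0.6 were recovered in 64.2% and 65.7%, changes of 1 in 91.0% and 95.5% and changes of 2 in 100%, with 8 and 11 false calls. A list shifted by -0.2 was called in each, with 0 other lists. Noise was drawn separately for each gene and few genes were changed, unlike in the real data. These runs therefore cannot show how the list tests or the false calls behave where genes vary together. A 2-fold rise put into the Cy3 signals of 200 loci in 2DAG gave a median log2 difference of 0.92.

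Each comparison lies on 1 slide of 4 arrays: 2DAG and 21DAG on one, Young and Mature leaves on the other. Alternatives for background correction, normalization, probe filter, probes per gene, arrays in the fit, replicate number, moderation, threshold and left-out arrays were run.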

Results

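Polysome association of mRNA was measured in Arabidopsis thaliana Columbia-0 with 8 two-colour arrays. On each array the Cy3 channel held RNA from the polysome fractions of a sucrose gradient and the Cy5 channel held RNA from all its fractions. The polysome ratio of a gene is its Cy3 over its Cy5 signal. The arrays fell into 4 groups of 2 biological replicates: whole plants 2 days after germination (2DAG), the above-ground part of plants 21 days after germination (21DAG), the newest 3 leaves of 21-day plants (Young leaves) and 3 older leaves other than cotyledons of 21-day plants (Mature leaves). The study set 2DAG against 21DAG and Young leaves against Mature leaves. Between 58.5% and 69.7% of gene probes were well above background in both channels of an array, with the lowest shares in Mature leaves, and no spot was saturated. Across 15665 genes, the log2 polysome ratios of replicate arrays correlated at 0.90 in 2DAG, 0.96 in 21DAG, 0.96 in Young leaves and 0.91 in Mature leaves. Arrays of different groups correlated at 0.62 to 0.95, so the replicate values alone do not set the groups apart. The number of arrays limits the precision of every value.

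The first question was whether the share of mRNA in polysomes differed between stages as a whole. Against the spike-in RNAs added to the fractions, the median log2 polysome ratio was -0.55 ± 0.05 (SD, n = 2) in 2DAG and -0.82 ± 0.11 (SD, n = 2) in 21DAG. The difference was 0.27, a 1.21-fold higher ratio in 2DAG, and both 2DAG arrays lay above both 21DAG arrays. The exact two-sided permutation test gave p = 0.333, the smallest that 2 against 2 arrays allow. The median was -0.84 ± 0.05 (SD, n = 2) in Young leaves and -0.80 ± 0.08 (SD, n = 2) in Mature leaves, and this difference of -0.04 lay within the spread between replicates (exact permutation p = 0.667). It turned to 0.12 without background correction and to 0.02 without the first Mature array. In the authors' deposited ratios, the array medians were 0.66 and 0.60 in 2DAG, 0.50 and 0.42 in 21DAG, 0.49 and 0.46 in Young leaves and 0.49 and 0.47 in Mature leaves. The changes of single genes below are relative to the bulk of genes on the same arrays. With arrays shifted to the spike-ins instead, the median gene moved by 0.27 in 2DAG against 21DAG and 99.6% of the genes called there were higher in 2DAG, and with the deposited ratios as given it moved by 0.43 and the share was 99.8%.

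**Figure D1:**
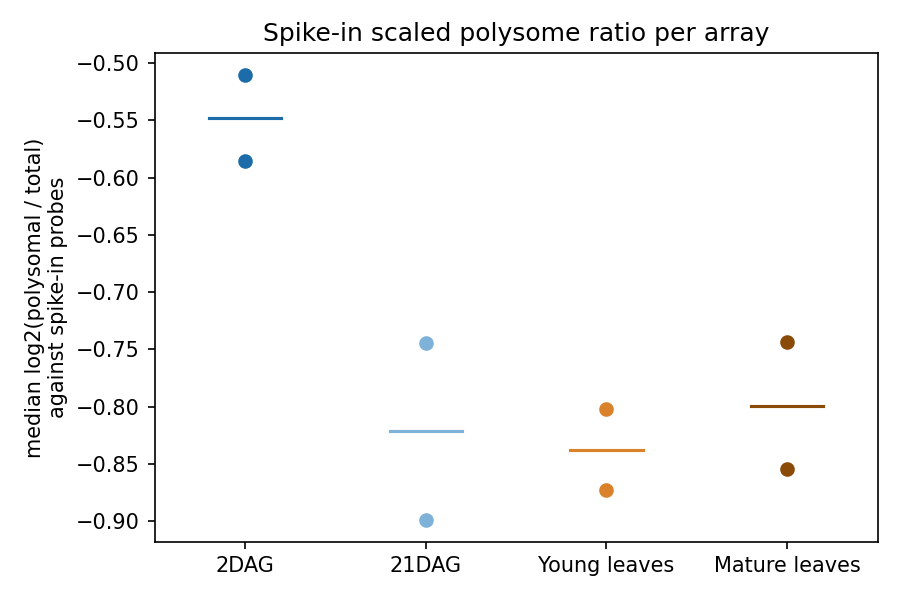
Median log2 polysomal over total ratio of all tested genes, less the mean over the spike-in probes, for each array (points) with the group mean (line), in the 4 groups. The 2DAG arrays lie above the arrays of the other 3 groups, and Young and Mature leaves overlap.

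MPL1 (AT5G14180), a lipase, had a log2 polysome ratio of -0.06 ± 0.07 (SD, n = 2) in 2DAG and -1.25 ± 0.06 in 21DAG, a 2.28-fold rise (limma adjusted p = 2.94e-06). The translationally controlled tumour protein gene TCTP (AT3G16640) was 2.12-fold higher in 2DAG (adjusted p = 6.57e-06, limma) and its second probe gave a log2 difference of 1.12 against 1.08. The ADP-ribosylation factor gene ARFA1E (AT3G62290) was 2.11-fold higher, the transcription factor gene BZIP9 (AT5G24800) 2.05-fold, the ubiquitin-conjugating enzyme gene UBC28 (AT1G64230) 1.97-fold, the ribosomal protein gene RPS15A (AT1G07770) 1.97-fold, the vesicle protein gene VAMP711 (AT4G32150) 1.92-fold and the ribosomal protein gene RPS18C (AT4G09800) 1.87-fold. In the opposite direction, the metallothionein genes MT1A (AT1G07600) and MT1C (AT1G07610) were 2.09-fold and 1.91-fold lower in 2DAG, with SEs of 0.21 and 0.17 on the log2 scale. RAP2.4 (AT1G78080), an AP2-type transcription factor gene, fell by 0.96 ± 0.06 (SE) on the log2 scale (limma adjusted p = 2.94e-06). Its second probe gave -0.44. The MYB-like gene RVE2 (AT5G37260) was 1.65-fold lower, the ferric reductase gene FRO6 (AT5G49730) 1.61-fold, LAF3 (AT3G55850) 1.61-fold, the thioredoxin gene TRX5 (AT1G45145) 1.59-fold and the arabinogalactan protein gene AGP21 (AT1G55330) 1.53-fold. The second probe of LAF3 went the other way, with a log2 difference of 0.23, and LAF3 did not pass without the first 2DAG array (-0.28, adjusted p = 0.0687), the first 21DAG array (-0.66, adjusted p = 0.0658) or the second (-0.71, adjusted p = 0.0701), nor with the mean of all probes (-0.23, adjusted p = 0.109). It was at -1.09 without the second 2DAG array. With the deposited ratios as given RVE2, TRX5 and AGP21 did not pass, at -0.11, -0.29 and -0.23 (adjusted p = 0.489, 0.0724 and 0.149). In all, 2451 of 15665 genes had a higher and 2436 a lower polysome ratio in 2DAG at the adjusted p threshold of 0.05, and the median size of the called changes was 0.28 on the log2 scale, with 17 genes past 2-fold. With the authors' deposited ratios centred on each array's median, an alternative chosen after seeing the data, 60.2% of the calls were higher in place of 50.2%. Without the second 21DAG array 1531 genes were called, without the first 2612, without the first 2DAG array 2883 and without the second 3230.

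**Figure D2:**
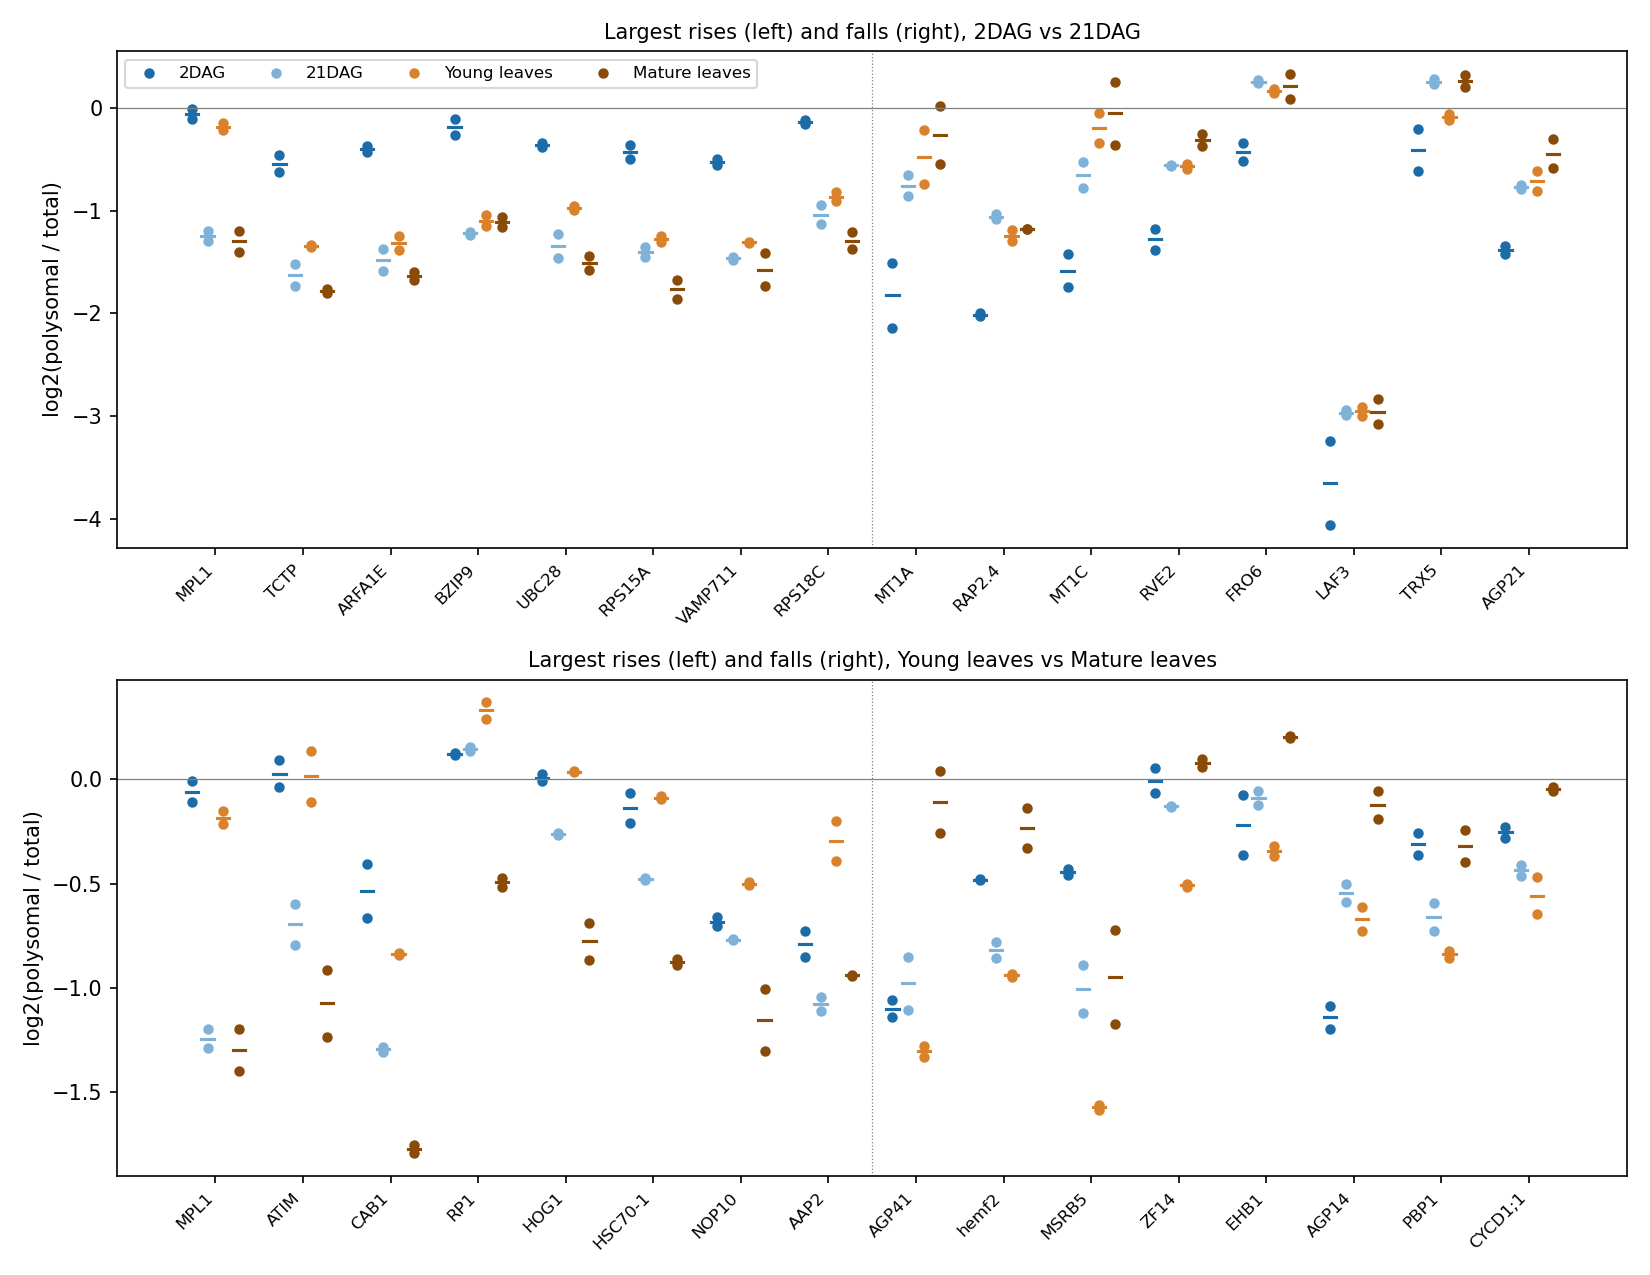
Log2 polysomal over total ratio after within-array normalization, per array (points) with group means (lines), for the genes with the largest rises and falls in 2DAG against 21DAG (top) and in Young against Mature leaves (bottom). Each gene shows all 4 groups, and MPL1 is higher in the first group of both comparisons. A gene's own dye effect is part of its level, so only differences between groups are read.

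Gene lists were tested relative to other genes with camera, while fry tested only whether a list's own genes changed. Of 201 cytosolic ribosomal protein genes, 88 rose and 21 fell in polysome ratio in 2DAG (92 and 22 adjusted over the list alone), with a median log2 difference of 0.18 (camera adjusted p = 2.01e-08; adjusted p = 0.693 with an estimated correlation). Of 51 genes of light harvesting and photosynthetic electron transport, 22 rose and 6 fell, with a median of 0.15 (24 and 8 adjusted over the list alone; adjusted p = 0.000142; adjusted p = 0.464 with an estimated correlation). The photosystem I antenna gene LHCA4 was 1.80-fold higher. Of 20 Calvin cycle genes, 10 rose and 2 fell, with a median of 0.19 (10 and 3 adjusted over the list alone). Its adjusted p was 0.0164, and adjusted p = 0.464 with an estimated correlation. The epimerase gene RPE was 1.58-fold higher. Of 25 core histone genes, 16 fell and none rose (18 adjusted over the list alone), with a median of -0.23 (camera adjusted p = 1.16e-05, and adjusted p = 0.464 with an estimated correlation). The H2A gene HTA6 fell by 0.35 on the log2 scale. Of 12 genes with conserved upstream open reading frames, 8 fell and 1 rose, with a median of -0.25 (9 and 2 adjusted over the list alone). Its adjusted p was 0.0199, and adjusted p = 0.495 with an estimated correlation. The magnesium/proton exchanger gene MHX was the one that rose, 1.31-fold. With fry, the photosynthesis, Calvin cycle and core histone lists passed (adjusted p = 0.00694 for each), as did upstream open reading frames (adjusted p = 0.0399). Cytosolic ribosomal proteins did not pass fry (adjusted p = 0.0994). With each array shifted to the spike-ins, the medians of the histone and upstream open reading frame lists turned to 0.07 and 0.05 while both stayed below the median gene. With the arrays' processed signals, the photosynthesis, Calvin cycle and upstream open reading frame lists had medians of 0.07, 0.14 and -0.23 and were not called (adjusted p = 0.142, 0.142 and 0.0669). The centred deposited ratios, which nearly repeat these signals, gave medians of 0.09, 0.15 and -0.22 and no call (adjusted p = 0.137, 0.148 and 0.0558). The last was not called with the mean of all probes (median -0.18, adjusted p = 0.0609). The Calvin cycle was not called with the spike-in shift (adjusted p = 0.05002), where its distance from the median gene was 0.22, the same as without it. Without the second 2DAG array its median was 0.12. Root markers moved with this comparison, as given with the total levels below.

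The remaining lists were not called by camera in the polysome ratio of 2DAG against 21DAG. Their median log2 differences were -0.07 for translation factors, -0.03 for ribosome biogenesis, -0.01 for plastid ribosomal proteins, -0.19 for the cell cycle and DNA replication, -0.04 for the proteasome, -0.11 for storage lipid mobilisation, -0.14 for cell wall expansion, -0.20 for leaf senescence, -0.06 for salicylate and pathogen defence, -0.03 for heat shock, -0.07 for the circadian clock and -0.19 for stomatal lineage markers. For translation factors, plastid ribosomal proteins and heat shock the mean and the test were positive, and for salicylate and pathogen defence the mean was positive while the test was negative. With fry, the cell cycle, leaf senescence and stomatal lineage lists passed as lower (adjusted p = 0.00629, 0.0354 and 0.0248). Single members of the lists not called by camera passed the gene-level test. The dyskerin homologue gene NAP57 fell by 0.24, the plastid ribosomal protein gene PSRP3/1 by 0.35, the proteasome ATPase gene RPT2a by 0.32, the peroxisomal thiolase gene PKT3 by 0.33, the expansin gene EXPA8 by 0.30, the clock gene ELF4 by 0.41 and the stomatal receptor gene TMM by 0.31 on the log2 scale. SAG21 was 1.54-fold, the cyclin-dependent kinase gene CDC2 1.38-fold and the chaperone gene HSC70-1 1.27-fold higher in 2DAG. From lists with too few genes for a test, the dehydrin gene RAB18 fell by 0.42 and the root beta-glucosidase gene PYK10 fell by 0.47. Each of the genes named here as falling, and HTA6, lay between 0.03 and 0.23 in the deposited ratios as given, where the median gene rose by 0.43. With the spike-in shift NAP57 was at 0.05 and the others lay between -0.18 and -0.0070, where none passed (adjusted p between 0.137 and 0.955). PYK10 was at -0.28 with processed signals. NAP57 did not pass with the mean of all probes (-0.17, adjusted p = 0.0515), without the first 2DAG array (-0.21, adjusted p = 0.102), the first 21DAG array (-0.20, adjusted p = 0.134) or the second (-0.29, adjusted p = 0.0596), nor EXPA8 without the second 21DAG array (-0.29, adjusted p = 0.0609). EXPA8 did not pass with processed signals (-0.22, adjusted p = 0.0685) or the centred deposited ratios (-0.21, adjusted p = 0.0772).

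Total RNA levels differed far more widely between 2DAG and 21DAG: for 19794 genes tested, 7356 were higher and 6682 lower in 2DAG. The 2 measures are not on equal terms. The ratio test kept only genes with signal in both channels on all 8 arrays. The total level test also kept genes with signal in only 1 group. The glyoxylate cycle gene ICL had a log2 level of 17.44 ± 0.03 (SD, n = 2) in 2DAG and 6.62 ± 0.50 in 21DAG, a log2 difference of 10.82 ± 0.24 (SE, limma adjusted p = 5.05e-09). MLS, of the same pathway, was 248-fold higher. The early light-induced genes ELIP1 and ELIP2 were 173-fold and 52.1-fold higher and the lipid transfer protein gene LTP2 78.4-fold higher in 2DAG. The ferric reductase genes FRO6 and FRO7 were 174-fold and 149-fold lower, the cold-regulated genes COR15A and COR15B 91.2-fold and 79.1-fold lower and ELI3-1 80.8-fold lower. Of 18 root markers, 17 rose in 2DAG, with a median log2 difference of 1.92 (camera adjusted p = 2.97e-07; adjusted p = 0.0488 with an estimated correlation). The Casparian strip gene CASP1 was 30.3-fold higher. All 8 flower and inflorescence markers fell, with a median of -1.62 (adjusted p = 0.000172; adjusted p = 0.162 with an estimated correlation), and AGL20 (SOC1) was 55.3-fold lower. Of 209 cytosolic ribosomal protein genes, 201 rose and 2 fell (median 1.14, adjusted p = 7.83e-22; adjusted p = 0.401 with an estimated correlation), RPL3B by 2.91-fold. All 35 proteasome genes rose (median 1.00, adjusted p = 9.18e-10, and adjusted p = 0.0405 with an estimated correlation), PBD2 by 2.43-fold. Of 37 cell cycle genes, 36 rose and 1 fell (median 0.99, adjusted p = 8.17e-09), the kinase gene AUR1 by 3.42-fold, and of 25 core histone genes 22 rose and 1 fell (median 0.72, adjusted p = 0.000104), HTA10 by 3.12-fold. Neither call held with an estimated correlation (adjusted p = 0.264 and 0.401). Of 51 light harvesting and electron transport genes, 44 fell and 2 rose (median -0.65, adjusted p = 8.17e-09), PSBQ-2 by 3.58-fold, and 13 of 20 Calvin cycle genes fell (median -0.70, adjusted p = 0.000228), CP12-2 by 12.5-fold. Both had an adjusted p of 0.401 with an estimated correlation. The other called lists were translation factors (33 rose, 2 fell, median 0.61, adjusted p = 8.07e-06, PAB4 1.85-fold), ribosome biogenesis (17 of 18 rose, median 0.99, adjusted p = 5.42e-05, the fibrillarin gene FIB2 5.52-fold) and plastid ribosomal proteins (20 rose, 2 fell, median 0.22, adjusted p = 0.00906, PSRP6 1.91-fold). These did not hold with an estimated correlation (adjusted p = 0.401, 0.401 and 0.534). Storage lipid mobilisation (12 of 16 rose, 2 fell, median 1.40, adjusted p = 0.000753), seed storage and late embryogenesis (18 of 20 rose, 2 fell, median 1.07, adjusted p = 0.000326, OLEO3 3.61-fold) and heat shock (6 of 8 rose, median 0.97, adjusted p = 0.0265, HSFA2 2.31-fold) were called too, but not with an estimated correlation (adjusted p = 0.145, 0.401 and 0.401). Without the second 2DAG array the plastid ribosomal protein and heat shock lists had medians of 0.17 and 1.01 and were not called (adjusted p = 0.0505 for both), nor was heat shock without the second 21DAG array (median 0.91, adjusted p = 0.0514). With the Cy5 signals scaled to the spike-ins, the median gene rose by 0.54 and 84.7% of calls were higher, in place of 52.4%. Plastid ribosomal proteins were then not called (camera adjusted p = 0.293). A fixed volume of spike-in was added to each pool. This shift therefore also follows the amount of extract and is not read as a change in mRNA per cell.

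Lists not called in total level between 2DAG and 21DAG had median log2 differences of -0.80 for leaf senescence, -0.37 for the circadian clock, -0.44 for salicylate and pathogen defence, 0.24 for shoot meristem markers, 0.11 for cell wall expansion, 0.07 for stomatal lineage markers and -0.03 for upstream open reading frame genes. The mean was positive for the last and negative for cell wall expansion, both with a positive test, and the test was negative for stomatal lineage markers. Single genes in them passed the test: the senescence regulator gene NAC6 was 5.12-fold, the clock gene PRR7 4.79-fold and bZIP1 2.66-fold lower, while XTH24 was 4.07-fold, KNAT1 3.48-fold, EDS5 3.40-fold and EPF2 3.03-fold higher in 2DAG.

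Young and Mature leaves of 21-day plants addressed how polysome association differs with leaf age. MPL1 was 2.17-fold higher in Young leaves (log2 ratio -0.18 ± 0.05 against -1.30 ± 0.14, SD, n = 2; limma adjusted p = 1.84e-05), a change also seen in 2DAG against 21DAG. It was smaller with processed signals (0.49, adjusted p = 0.0185) and the centred deposited ratios (0.47, adjusted p = 0.0212), and did not pass with the deposited ratios as given (0.43, adjusted p = 0.105). ATIM, a TIMELESS homologue (AT5G52910), was 2.13-fold, the chlorophyll a/b-binding protein gene CAB1 (AT1G29930) 1.92-fold and RP1 (AT1G43170), a ribosomal protein gene, 1.77-fold higher (limma adjusted p = 2.12e-05 for RP1). The second probe of CAB1 gave a log2 difference of 0.55 against 0.94, and processed signals gave 0.60. The S-adenosylhomocysteine hydrolase gene HOG1 (AT4G13940) was 1.76-fold higher, although its second probe gave a log2 difference of 0.09. The chaperone gene HSC70-1 (AT5G02500) was 1.73-fold, the small nucleolar ribonucleoprotein gene NOP10 (AT2G20490) 1.58-fold and the amino acid permease gene AAP2 (AT5G09220) 1.57-fold higher. AAP2 did not pass with the deposited ratios as given (0.40 in place of 0.65, adjusted p = 0.156). AGP41 (AT5G24105), an arabinogalactan protein gene, was 2.29-fold lower in Young leaves (log2 ratio -1.31 ± 0.04 against -0.11 ± 0.21, SD, n = 2; limma adjusted p = 4.05e-05). hemf2 (AT4G03205) was 1.63-fold, the methionine sulfoxide reductase gene MSRB5 (AT4G04830) 1.54-fold, ZF14 (AT1G58340) 1.50-fold, EHB1 (AT1G70800) 1.46-fold, AGP14 (AT5G56540) 1.46-fold, the PINOID-binding gene PBP1 (AT5G54490) 1.43-fold and the cyclin gene CYCD1;1 (AT1G70210) 1.43-fold lower. AGP14 lost this direction with the arrays' processed signals, where its log2 difference was 0.05, and with the centred deposited ratios (0.02). With processed signals hemf2 and CYCD1;1 were at -0.29 and -0.30, in place of -0.71 and -0.51, and did not pass (adjusted p = 0.364 and 0.117). MSRB5 did not pass there either (-0.57 in place of -0.62, adjusted p = 0.0576), nor without the first Young array (-0.64, adjusted p = 0.0524), and was at -0.40 without the second Mature array. With the centred deposited ratios hemf2, MSRB5 and CYCD1;1 did not pass, at -0.31, -0.59 and -0.33 (adjusted p = 0.330, 0.0507 and 0.0907). With those as given hemf2 and CYCD1;1 were at -0.34 and -0.36 (adjusted p = 0.299 and 0.253). ZF14 and EHB1 were larger with the centred deposited ratios, at -1.73 and -1.15. In all, 560 genes rose and 747 fell among 15665, with 4 past 2-fold. The count fell to 226 without the first Young array and 399 without the second, to 748 in a fit of these 4 arrays alone, and to 830 with processed signals, where 60.4% of calls were higher in place of 42.8%; that share was 57.1% with median centring and 54.4% with the centred deposited ratios.

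Of 41 translation factor genes, 16 rose in polysome ratio in Young leaves and none fell (20 and 1 adjusted over the list alone), with a median log2 difference of 0.17 (camera adjusted p = 3.36e-12; adjusted p = 0.0479 with an estimated correlation), and the initiation factor gene EIF4A1 was 1.50-fold higher. Of 17 ribosome biogenesis genes, 6 rose and none fell (11 adjusted over the list alone), with a median of 0.20. Its camera adjusted p was 5.63e-07, and adjusted p = 0.153 with an estimated correlation. The stomatal lineage and cell cycle lists moved in total level between these leaves, as given below. Of 201 cytosolic ribosomal protein genes, 50 rose and 2 fell (61 and 3 adjusted over the list alone), with a median of 0.09 (adjusted p = 4.43e-10). This call held neither with an estimated correlation (adjusted p = 0.5997) nor with fry (adjusted p = 0.206). It was also lost without the first Mature array, where the median was 0.007 (adjusted p = 0.0931), and without the second Mature array the median was 0.18. Of 17 cell cycle genes, 4 rose and 1 fell (9 and 2 adjusted over the list alone), with a median of 0.17 (adjusted p = 0.000487; adjusted p = 0.121 with an estimated correlation), while the cyclin gene CYCD3;1 fell by 0.35. Of 20 Calvin cycle genes, 3 rose and 1 fell (4 and 2 adjusted over the list alone), with a median of 0.06 (adjusted p = 0.0418; adjusted p = 0.463 with an estimated correlation), and GAPA was 1.44-fold higher. The cell cycle and Calvin cycle lists were not called with median centring, where their medians were 0.13 and 0.07 (adjusted p = 0.326 and 0.746), nor was the latter without the second Young array (median 0.05, adjusted p = 0.139) or the first Mature array (median 0.10, adjusted p = 0.0931). Without the first Young array the Calvin cycle median was also 0.10. GAPA and CYCD3;1 did not pass without the first Young array (0.52 and -0.31, adjusted p = 0.05005 and 0.0889), nor CYCD3;1 with processed signals (-0.21, adjusted p = 0.0854), the spike-in shift (-0.33, adjusted p = 0.0660) or the deposited ratios as given (-0.25, adjusted p = 0.590) or centred (-0.22, adjusted p = 0.0782).

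Lists not called here had median log2 differences of 0.00 for core histones, -0.06 for light harvesting and electron transport, -0.05 for plastid ribosomal proteins, 0.04 for the proteasome, 0.08 for storage lipid mobilisation, -0.02 for upstream open reading frame genes, 0.03 for cell wall expansion, 0.05 for leaf senescence, -0.01 for salicylate and pathogen defence, -0.05 for heat shock, -0.14 for the circadian clock and 0.06 for stomatal lineage markers. With fry, plastid ribosomal proteins passed as lower (adjusted p = 0.0216). The mean was negative for cell wall expansion and positive, as was the camera test, for heat shock. Among their members, the plastid ribosomal protein gene RPL4 was 1.33-fold, SAG21 1.30-fold, the proteasome gene RPN10 1.22-fold and TMM 1.17-fold higher in Young leaves, and the expansin gene EXPA5 fell by 0.33. None of these 5 passed without the first Young array, where their log2 differences were 0.40, 0.37, 0.27, 0.20 and -0.35 (adjusted p = 0.0502, 0.0553, 0.189, 0.282 and 0.0661). RPN10, TMM and EXPA5 did not pass without the second Young array either (0.29, 0.24 and -0.30), nor RPN10 and TMM without the second Mature array (0.27 and 0.18). With processed signals SAG21, RPN10, TMM and EXPA5 did not pass, at 0.14, 0.25, 0.017 and -0.16 (adjusted p = 0.220, 0.130, 0.912 and 0.227). With the spike-in shift RPN10, TMM and EXPA5 did not pass, at 0.30, 0.24 and -0.31 (adjusted p = 0.102, 0.248 and 0.0979). With the deposited ratios as given RPL4, SAG21, RPN10 and EXPA5 did not pass, at 0.45, 0.099, 0.21 and -0.19 (adjusted p = 0.0862, 0.944, 0.714 and 0.764), and TMM was at -0.03. With these centred SAG21, RPN10 and EXPA5 did not pass either (adjusted p = 0.256, 0.154 and 0.217). TMM, at an adjusted p of 0.0488, also did not pass without background correction (0.21, adjusted p = 0.0752), with median centring (0.19, adjusted p = 0.135) or with no filter of dim probes (adjusted p = 0.0821). Nor did it pass in a fit of the arrays compared (adjusted p = 0.0946), or in that fit with the filter also set on those arrays (adjusted p = 0.0967).

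**Figure D3:**
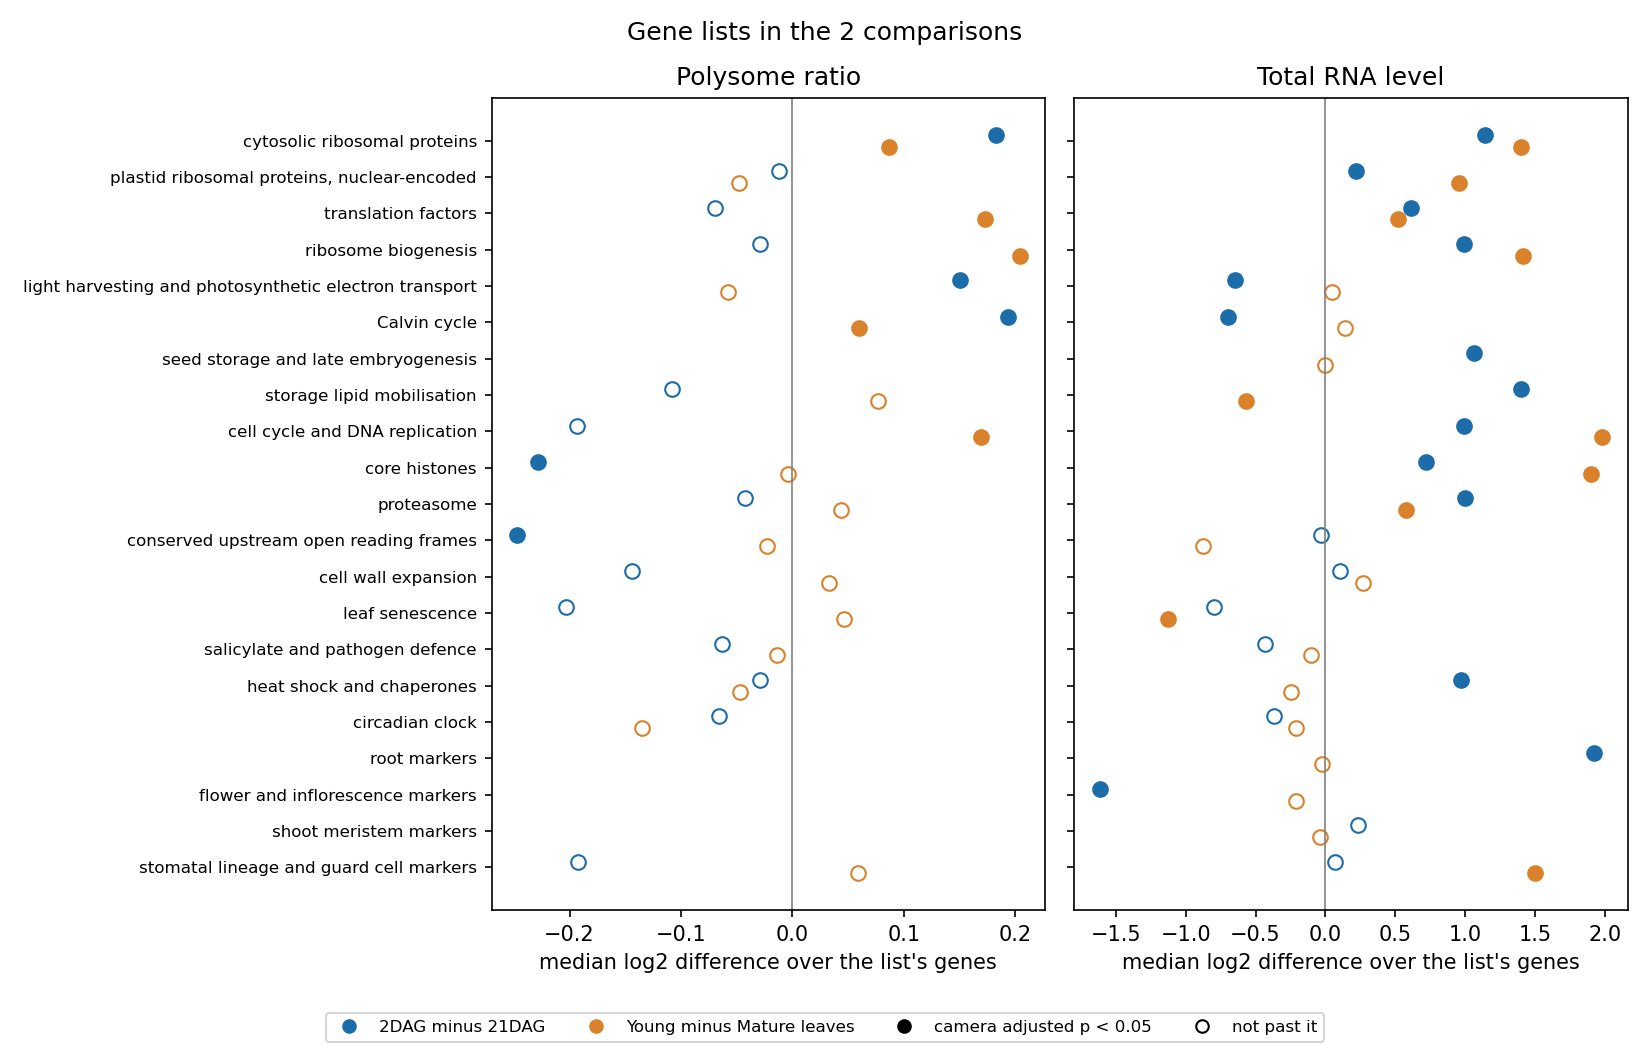
Median log2 difference over the genes of each fixed list, in the polysome ratio (left) and the total RNA level (right), for 2DAG minus 21DAG and Young minus Mature leaves. Filled points passed camera with a preset correlation. Lists without a point had fewer than 4 tested genes. Cytosolic ribosomal proteins lie above 0 in all 4 cases, and core histones lie below 0 in the 2DAG ratio, at 0.07 with the spike-in shift, while their total level was higher.

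In total RNA, 6293 genes rose and 6383 fell in Young leaves among 19794. GER3, a germin-like gene, was 207-fold higher, with SDs of 0.47 and 1.51 on the log2 scale. MLP423 was 125-fold, LTP6 59.4-fold, XTH9, a cell wall enzyme gene, 43.2-fold and ENODL14 34.6-fold higher. AAP4, an amino acid permease gene, was 32.3-fold, the nicotianamine synthase gene NAS1 31.4-fold, GRP3S 26.2-fold, the jasmonate synthesis gene AOC1 22.7-fold and NAC6 21.6-fold lower. Of 209 cytosolic ribosomal protein genes, 200 rose and 1 fell (median 1.40, camera adjusted p = 2.37e-31), RPS6 by 5.64-fold, and 38 of 39 plastid ribosomal protein genes rose (median 0.96, adjusted p = 1.02e-12), EMB3113 by 2.66-fold. These calls did not hold with an estimated correlation (adjusted p = 0.316 and 0.240). Of 37 cell cycle genes, 35 rose and 1 fell (median 1.98, adjusted p = 2.39e-15), PRL (MCM7) by 8.28-fold, and of 25 core histone genes 23 rose and 1 fell (median 1.90, adjusted p = 2.26e-10), HTA13 by 5.69-fold. Neither held with an estimated correlation (adjusted p = 0.135 and 0.240). The lists of ribosome biogenesis (17 of 18 rose, median 1.41, adjusted p = 2.96e-07, FIB2 7.91-fold), the proteasome (32 of 35 rose, median 0.58, adjusted p = 5.99e-08, RPT2b 2.27-fold) and stomatal lineage markers (8 of 9 rose, median 1.50, adjusted p = 0.000758, TMM by 3.34 on the log2 scale) were called as higher. With an estimated correlation they were not (adjusted p = 0.315, 0.0670 and 0.254). Translation factors were called as well (32 rose, 3 fell, median 0.52, adjusted p = 5.35e-06; adjusted p = 0.330 with an estimated correlation), although ELF5A-3 was 5.69-fold lower. Leaf senescence genes were lower (11 of 14 fell, 1 rose, median -1.13, adjusted p = 0.000834), as were storage lipid mobilisation genes (11 of 16 fell, median -0.57, adjusted p = 0.00208), CSY3 by 2.81-fold. Both had an adjusted p of 0.135 with an estimated correlation. With Cy5 scaled to the spike-ins, the medians of these 2 lists turned to 0.28 and 0.69, still under the median gene, and the latter was not called (adjusted p = 0.0633), nor did CSY3 pass (-0.13, adjusted p = 0.662). With Cy5 scaled to the spike-ins the median gene rose by 1.16 and 97.5% of calls were higher, in place of 49.6%.

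Lists not called in total level between the leaves had medians of 0.04 for light harvesting and electron transport, 0.14 for the Calvin cycle, -0.88 for upstream open reading frame genes, 0.27 for cell wall expansion, -0.10 for salicylate and pathogen defence, -0.25 for heat shock, -0.21 for the circadian clock, -0.03 for root markers, -0.21 for flower markers and -0.04 for shoot meristem markers, and seed storage genes had a median near 0. For root markers the mean and the test were positive. Among their members, EXPA6 was 5.89-fold, LHCB4.3 3.63-fold, EMB3119 2.39-fold and SHR 1.46-fold higher in Young leaves, while HSF4 was 3.91-fold, RAB18 3.17-fold, HSP90.1 2.69-fold, PAD4 2.28-fold, AGL20 2.05-fold and PRR7 1.52-fold lower. With Cy5 scaled to the spike-ins the last 3 turned to log2 differences of 0.11, 0.46 and 0.78, and RAB18 and HSP90.1 did not pass, at -0.29 and -0.20 (adjusted p = 0.306 and 0.474). PRR7 was at -0.40 without the second Mature array, in place of -0.60.

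The polysome ratio changes of the 2 comparisons were nearly uncorrelated across 15665 genes (Pearson r = -0.003, Spearman rho = -0.10, described without a p because genes are not independent replicates). Pearson r was 0.14 with the first array of each group alone and -0.18 with the second. Of 590 genes called in both, 246 were higher in 2DAG and in Young leaves against 87.6 for independent lists, and 70 were lower in both against 116. Higher in 2DAG and lower in Young leaves were 216 against 117, and 58 were the reverse against 87.1. Both calls of a gene use the same estimate of its spread and the same filter. They are therefore not independent, and no conclusion is drawn from the distance to these expected counts. A test of the difference between the 2 changes called 2020 genes with a larger and 1613 with a smaller change in 2DAG against 21DAG (55.6% larger). That share was 99.5% with the spike-in shift, 99.8% with the deposited ratios as given, 69.1% with these centred and 41.1% with median centring. The count was 2015 and 1441 without the first and second 21DAG array and 1473 and 2190 without the first and second Young array. Light harvesting and electron transport genes differed by a median of 0.18 (21 larger, 4 smaller, camera adjusted p = 0.000311), translation factors by -0.21 (3 larger, 16 smaller, adjusted p = 0.000311), ribosome biogenesis by -0.25 (none larger, 5 smaller, adjusted p = 0.000354), core histones by -0.23 (none larger, 7 smaller, adjusted p = 0.000483) and the cell cycle by -0.33 (2 larger, 10 smaller, adjusted p = 0.00375), and with an estimated correlation their adjusted p lay between 0.209 and 0.456. The first was not called with processed signals (median 0.05, adjusted p = 0.218) or the centred deposited ratios (median 0.07, adjusted p = 0.228), nor the last with median centring (median -0.27, adjusted p = 0.0791). The other lists were not called for a difference, cytosolic ribosomal proteins among them, with a median of 0.07. The polysome ratio change was weakly related to the total level change measured on other arrays, with r = -0.11 across genes in 2DAG against 21DAG and r = 0.13 in Young against Mature leaves.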

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

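The tests of technical explanations below were written before their results were seen, after the list changes themselves were known. The change in polysome ratio differed between the 2 comparisons, by an interaction test in limma, for 3633 genes. Values below are the change in 2DAG against 21DAG minus that in Young against Mature leaves, on the log2 scale. By gene list, the median difference was -0.21 for translation factors, -0.25 for ribosome biogenesis, 0.18 for light harvesting and photosynthetic electron transport, -0.33 for the cell cycle and -0.23 for core histones. None of these 5 lists passed with an estimated correlation, where the adjusted p lay between 0.209 and 0.456. Genes named in the ratio comparisons were picked for their change in 1 of these, which favours a difference, so the share that differed is not read. Those below differed at an adjusted p under 0.05. Larger values in 2DAG against 21DAG were found for MSRB5 (1.18), AGP41 (1.07), hemf2 (1.05), BZIP9 (1.02), PBP1 (0.87), LHCA4 (0.80), ARFA1E (0.76), ZF14 (0.71), CYCD1;1 (0.70), VAMP711 (0.68), TCTP (0.64), EXPA5 (0.62), RPE (0.49), RPS15A (0.48), RPS18C (0.47), UBC28 (0.44), EHB1 (0.42), CYCD3;1 (0.39) and CDC2 (0.38). Smaller values were found for RAP2.4 (-0.89), RP1 (-0.85), MT1C (-0.79), FRO6 (-0.64), PYK10 (-0.59), NOP10 (-0.57), HOG1 (-0.54), TMM (-0.53), EIF4A1 (-0.51), RVE2 (-0.46), PKT3 (-0.46), HSC70-1 (-0.45), RPN10 (-0.40), RAB18 (-0.40), HTA6 (-0.39), RPT2a (-0.38), PSRP3/1 (-0.37), AAP2 (-0.36), RPL4 (-0.34), EXPA8 (-0.32) and NAP57 (-0.30).

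The first pattern weighed was the higher polysome ratio of cytosolic ribosomal protein mRNAs in 2DAG. It was not called with an estimated correlation (adjusted p = 0.693) or with fry (adjusted p = 0.0994). Against the 50 genes nearest in signal intensity the list stayed higher by 0.25 on the log2 scale, against those nearest in total-level change by 0.25, and against those nearest in genomic span by 0.16, with 0.21 unmatched and the same sign in all 4 pairings of arrays. Genes with shorter spans tended to rise (Spearman rho = -0.22), and the value matched on span argues against genomic span as the whole cause. Transcript and coding lengths were not available, so transcript length stays untested. Genes with a higher total level, measured on the same Cy5 signal, tended to fall (rho = -0.12), so transcript level pointed the other way. Intensity had little relation to the change across all genes after loess (rho = -0.01). This need not hold for genes as bright as this list (median log2 intensity 12.70 against 9.09). The match on intensity did not lower the list's shift, and no more is concluded from it. The estimated correlation among these genes was 0.44, and root tissue in 2DAG, with 17 of 18 root markers higher, and growth stage stay open as untested.

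The second pattern was the lower ratio of core histone mRNAs in 2DAG, not called with an estimated correlation (adjusted p = 0.464). The list stayed lower by -0.22 against genes matched on intensity, -0.20 on total-level change and -0.21 on genomic span, with -0.20 unmatched and the same sign in all 4 pairings. The match on total level argues against transcript level as the whole cause. Histone genes have short spans (9.73 against 11.27 log2 bp), and genes with short spans tended to rise, so span pointed the other way beforehand. Transcript length was not tested. Intensity again had little relation to the change across all genes, and no conclusion is drawn from that match. Tissue composition and stage stay open, since both differ between the same groups.

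The third pattern was the higher ratio of translation factor mRNAs in Young leaves. The list stayed higher by 0.16 against genes matched on intensity, 0.12 on total-level change and 0.19 on genomic span, with 0.18 unmatched and the same sign in all 4 pairings. The match on total level (rho = 0.14) argues against transcript level as the whole cause. Intensity had little relation to the change across all genes (rho = 0.04). The list's span was near that of other genes (11.32 against 11.26 log2 bp). These 2 matches therefore decide little. Leaf age, by design, and tissue composition stay open: in total level 8 of 9 stomatal lineage markers and 35 of 37 cell cycle genes were higher in Young leaves (adjusted p = 0.254 and 0.135 for the lists with an estimated correlation).

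Data outside the comparisons also carried signal: of 9211 probes without a locus, 2445 were well above background in both channels on all 8 arrays. In a separate fit of these probes with the same model, 635 changed in polysome ratio between 2DAG and 21DAG and 230 between the leaves. Among genes with a locus, 31.2% and 8.34% were called.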

How the results depend on the processing

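Alternatives using the deposited ratios centred on each array's median, and the median centring of Cy5 for total levels, were chosen after seeing the data. The centred deposited ratios nearly repeat the processed signals and add no separate check. For the total level, each alternative kept the number of genes called within 1.5 times the main count. The genes behind a count could still change. With Cy5 scaled to the spike-ins, 2495 of the 14038 main calls in 2DAG against 21DAG had the opposite sign. Between the leaves 5407 of 12676 did. The polysome ratio counts moved more. With a spike-in shift after loess the genes called numbered 8962 in 2DAG against 21DAG, 487 in Young against Mature leaves and 5695 for the difference between them, and with the deposited ratios as given 11089, 310 and 8071; by construction the first keeps the shift of all genes that loess removes, and why both lowered the leaf count was not tested. In the difference, 99.5% and 99.8% of those calls were higher, in place of 55.6%. With processed signals 830 genes were called between the leaves and 2259 for the difference, and with the centred deposited ratios 790 and 2170 (69.1% higher); median centring gave 41.1% higher for the difference. The cause was not tested. Between the leaves, a fit of the compared arrays alone gave 748, and the same fit with the filter also set on those arrays gave 738. A threshold of 0.10 gave 2335. Leaving out 1 array gave 1531 to 3230 genes in 2DAG against 21DAG, 226 to 1930 in the leaves and 1441 to 5053 for the difference; the group left with 1 array is then assumed to vary like the others. Leaving out Mature replicate 1 raised the leaf count to 1930. For total levels the range was 12393 to 12930 and 11058 to 11863. Lists called fell with an estimated correlation from 5 to 0, from 5 to 1 and from 5 to 0 in the ratio comparisons and their difference, and from 14 to 2 and from 10 to 0 in total level. Such a loss need not come from members that vary together. For the proteasome in total level between the leaves, the estimated correlation was 0.0022. Its unadjusted camera p still rose from 1.43e-08 to 0.00319. With fry 7, 5 and 8 lists were called in the ratio comparisons and their difference, and 17 and 15 in total level. These were not all the same lists, and cytosolic ribosomal proteins did not pass fry in either ratio comparison. Fry does not set a list against other genes, so its counts answer another question than those of camera. With processed signals 2 lists were called in the ratio of 2DAG against 21DAG, and with median centring 9 for the difference. With camera at its preset correlation, under all alternatives of processing, model fit and left-out arrays, the test of each called list kept its direction, with 523 calls kept and 24 lost. For named genes 1631 calls were kept and 73 lost. Fitting only the arrays compared does not apply to the difference, which uses all 8. The spike-in scaled difference between leaves turned from -0.04 to 0.12 without background correction, and lay between -0.094 and 0.017 with 1 array left out, so its sign is not settled. That of 2DAG against 21DAG lay between 0.20 and 0.35 with 1 array left out.

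Named genes changed sign in 18 cases. Under the deposited ratios as given, in which the median gene rose by 0.43 in 2DAG, the log2 values became 0.084 for PSRP3/1, 0.13 for NAP57, 0.11 for RAB18, 0.15 for PKT3, 0.071 for HTA6, 0.10 for RPT2a, 0.23 for EXPA8, 0.033 for ELF4, 0.16 for PYK10 and 0.041 for TMM, and NAP57 was 0.054 with the spike-in shift. Between leaves, TMM was -0.030 with those ratios and -0.00023 once centred, and AGP14 was 0.053 with processed signals and 0.024 with the centred ratios. In total level with Cy5 scaled to the spike-ins, PAD4 became 0.11, PRR7 0.78 and AGL20 0.46. Whether same-numbered arrays share more than a number is not stated in the labels. Their deviations from the group means correlated at 0.16 in the ratio of 2DAG and 21DAG and 0.23 in that of the leaves, and at 0.00 and 0.45 in total level, where those of 21DAG correlated at 0.59 with Young and 0.57 with Mature leaves. With the replicate block 5376, 1734 and 4161 genes were called in the ratio and its difference, and 14467 and 13194 in total level. A slide block was not run, since each comparison lies on 1 slide and the term cancels. Mature leaves had the lowest signal over background, which limits what could be tested there.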

Other observations

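Genes with longer genomic spans had a different polysome ratio change from shorter ones, and in opposite directions in the 2 comparisons; this was looked at after the results were seen. Across genes, which are not independent replicates, the Spearman correlation of span with the change was -0.22 in 2DAG against 21DAG, between -0.29 and -0.14 over the 4 pairings of arrays. Of the 3915 genes with the longest spans, 250 rose and 993 fell in 2DAG, and of the 3918 with the shortest spans 844 rose and 539 fell. In Young against Mature leaves the correlation was 0.28, but between 0.04 and 0.39 over the pairings, and with processed signals its lowest pairing was -0.01, so it depends on which arrays are compared. There, 161 of the longest genes rose and 55 fell, while 123 of the shortest rose and 375 fell. No explanation was tested.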
